A study of Solanum tuberosum with 11 samples.

How the data were processed

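RNA was measured by sequencing in discs of potato (Solanum tuberosum, cultivar Atlantic) periderm that held the apical bud, cut from dormant greenhouse minitubers. Per the labels, intact tubers were injected with 5 µl of dimethyl sulfoxide (DMSO, the solvent) alone or with 10 µg of the nitroguanidine compound NG, 1-(alpha-ethylbenzyl)-3-nitroguanidine. The labels list 11 libraries: 3 of DMSO tubers at zero time, and 3, 2 and 3 of NG tubers at day 1, day 4 and day 7. No DMSO library at a later time is among them, so the effect of NG and the effect of elapsed time cannot be separated in any comparison, including those between NG days.

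The values come from a single table in which the authors had already combined their libraries into 1 value per condition. It lists 35091 transcripts, 1 per gene, on 12 chromosomes, under 4 conditions called Controls, NG 1-Day, NG 5-Days and NG 7-Days, and gives all 6 comparisons between them. No label names a day 5. The condition the table calls NG 5-Days was therefore kept under that name and was not equated with the day 4 libraries, and how many libraries stand behind each condition is not given in the sources used here.

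Per the file headers, the layout is that of a Cuffdiff differential expression table. Each line holds the authors' level in both conditions, a log2 fold change, a test statistic, the authors' deposited p-value and q-value, and a yes or no call. The unit of the levels is not named in the header or the labels; this layout usually holds FPKM (fragments scaled to transcript length and library size), and the values are called levels here. The aligner, software versions, genome build and filters are not given in the sources used here, and coordinates are those of the deposited table. Sequencing depth per library is unknown, so no interval or detection floor that needs depth was computed.

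The properties of the deposited test were worked out from its values. Benjamini-Hochberg adjustment of the deposited p-values over all 118862 tested lines of the 6 comparisons together gave the deposited q-values to within 3.32e-06, so the number of calls in 1 comparison depends on the other 5. The p-values are 2-sided normal tails of the statistic, to within 2.85e-06. The highest p-value called was 0.00297. Because the squared ratio of log fold change to statistic is a sum of a term for each condition, a standard error per transcript and condition could be solved for 18223 transcripts, with a median relative residual of 1.67e-06. These errors are the authors' model errors, not a spread between libraries computed here, and nothing in the sources says whether libraries came from separate tubers. The table has no replicate values, so no mean ± SD or n is given for any level.

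Changes to the planned design were forced by the table. The edgeR, limma and gene list tests fixed before the data were examined need a value per library and could not be run, so the authors' deposited test at an adjusted p under 0.05 is the test reported. For the same reason no library could be left out, no replicate block could be fitted and no other split of the libraries could be drawn. The 30 gene lists fixed beforehand (hormone response, cell division, storage proteins, stress and others) rely on gene descriptions. The deposited table pairs its identifiers with no names, and 0 of them matched the 32873 genes of the reference table for assembly SolTub_3.0, so none of the lists could be tested and no gene name is given.

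The rule for named transcripts was fixed beforehand as the greatest rises and falls among called genes with a level of at least 5 in the higher condition. Its requirements on libraries and descriptions could not be applied, and the number was cut to at most 2 rises and 2 falls in each comparison with the control. Folds against a condition listed at 0 were left out of medians. Of the transcripts, 13 were left out of level summaries, 8 because their lines disagreed on a level and 5 because the table marks them as too abundant to process. The table also lists some transcripts at high levels as not tested, by a rule not given in the sources used here. Many lines marked as not tested still carry a p-value below 1, 5725 of them for NG 7-Days against the control, and the alternative without a filter on low levels adjusted these too.

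Whether transcripts called in the same direction lie side by side was tested by shuffling calls 10000 times within 10 classes of level, counting pairs that do not overlap and are adjacent among the tested transcripts. Unchanged conditions against the shared control were simulated from the recovered errors of 17673 transcripts. On simulated data with known changes in those transcripts, the adjusted test recovered 4% of 2-fold and 41% of 4-fold changes for NG 5-Days against the control, and 44% and 85% for NG 5-Days against NG 1-Day. All recovered changes had the right direction. Only 100 transcripts per size of change were altered, and in NG 5-Days alone. With so few changes the adjustment set a stricter bound than in the deposited table, so these shares understate the recovery there. The neighbour test, run on the 19517 transcripts tested for NG 1-Day against the control, gave a permutation p of 0.000999 for planted pairs and 0.983 for random calls.

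Alternatives covered the threshold, a fold minimum, filters on level, median centring, quantile normalization, pseudocounts of 0.1, 1 and 5, the set of comparisons adjusted together, overlapping loci and the error of the control. Those on scaling, pseudocount and control error used a normal test on the levels and recovered errors. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.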

Results

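The data describe the tip of dormant potato minitubers after injection of NG, at the times the labels and the deposited table give. Potato tubers are dormant for a period after harvest, during which their buds do not grow; the labels call the injected tubers dormant. The question was which transcripts changed at each time after NG. By the authors' deposited table, 17402 transcripts had a level of at least 1 in the control, 16845 in NG 1-Day, 17374 in NG 5-Days and 17696 in NG 7-Days. The summed levels lay between 613251 and 642599 per condition, and the 100 most abundant transcripts took between 21.2% and 24.2% of the sum. There are no replicate values, so each error below is the standard error that the authors' test used.

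One day after NG the calls against the DMSO control were nearly all downward. Among 19517 tested transcripts 201 fell and 5 rose in the authors' deposited table, at an adjusted p under 0.05. The falls were steep, with a median log2 fold change of -3.54, an 11.6-fold lower level, and the 5 rises had a median of 1.45. PGSC0003DMG400031140, at chromosome 4, 53285510 to 53288554, fell from 22.7 to 0.384 in the authors' deposited table (log2 fold change -5.89, standard error 0.84, adjusted p = 2.76e-10). PGSC0003DMG400015601, at chromosome 5, 6805857 to 6808558, fell from 7.98 to 0.121 in the authors' deposited table (log2 fold change -6.05, standard error 0.94, adjusted p = 1.12e-08). In NG 7-Days these transcripts were at 58.3 and 18.9. The control was close to an average of NG 1-Day and NG 7-Days, as described below. Under such a relation NG 1-Day can lie far below the control but only moderately above it. The excess of falls is therefore not separate evidence of a mainly downward response to NG.

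The rises at day 1 were smaller and included abundant transcripts. PGSC0003DMG400030771, at chromosome 6, 37193129 to 37195390, rose from 321 to 909 in the authors' deposited table (2.83-fold, log2 standard error 0.42, adjusted p = 0.00802). PGSC0003DMG400004940, at chromosome 4, 58909083 to 58909681, rose from 15.4 to 61.0 in the authors' deposited table (log2 fold change 1.98, standard error 0.63, adjusted p = 0.0331), and this call was lost at an adjusted p under 0.01. When the comparison was adjusted alone, 82 transcripts were called, and all 82 had fallen, so each of the 5 rises lost its call. The authors' deposited table calls all 5 transcripts that rose lower in NG 5-Days than in NG 1-Day. They were selected for a high NG 1-Day value, which that test uses again, so a fall was favoured by the selection. The 201 that fell had a median level of 0.315 on day 1 in the authors' deposited table, and with a pseudocount of 5 the comparison gave 11 calls, 7 of them rises.

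The transcripts that fell at day 1 did not stay low. Of the 201, the authors' deposited table has 118 above the control in NG 5-Days and all 201 above the control in NG 7-Days. Their median log2 level relative to the control went from -3.54 in NG 1-Day to 1.34 in NG 5-Days and 1.08 in NG 7-Days, where the interquartile range was 0.90 to 1.39. From NG 1-Day to NG 5-Days 155 of the 171 that were tested rose, and from NG 1-Day to NG 7-Days 98 of the 98 that were tested, by the authors' deposited table. The 201 were selected for a low NG 1-Day value, which these 2 comparisons use again, so a rise from it was favoured by the selection and the counts are not separate evidence of recovery. None of the 98 that were tested for NG 7-Days against the control passed that test, so their higher level on day 7 is a shared direction and not a set of calls. The control was also close to an average of NG 1-Day and NG 7-Days, as described below. Under such a relation, a level below the control on day 1 goes with one above it on day 7. The shared direction is therefore not separate evidence of an overshoot.

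**Figure D1:**
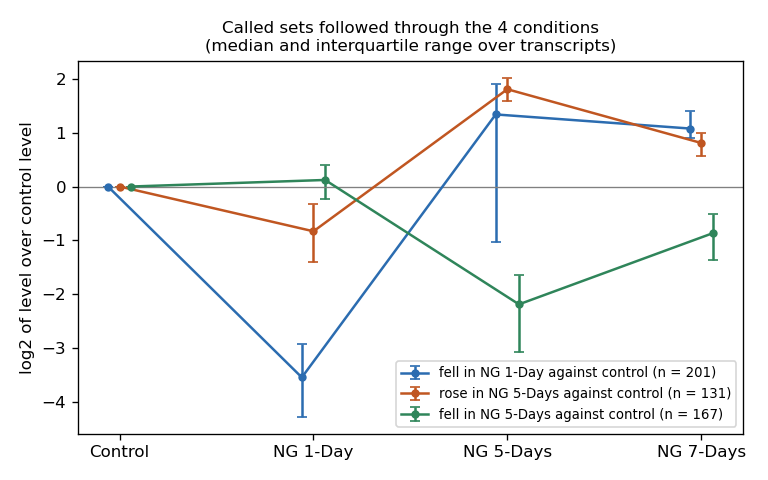
Median log2 level relative to the DMSO control (y axis) in the 4 conditions (x axis) for 3 called sets, with bars for the interquartile range over transcripts, not over libraries. The 201 transcripts that fell in NG 1-Day reach -3.54 there and 1.08 in NG 7-Days, and the set that rose in NG 5-Days goes from 1.80 there to 0.81 in NG 7-Days.

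In the condition the table calls NG 5-Days, transcripts moved both ways against the control. Among 20223 tested, 131 rose and 167 fell in the authors' deposited table, with median log2 fold changes of 1.80 and -2.18. PGSC0003DMG400021289, at chromosome 10, 2210017 to 2210287, rose from 3.23 to 136 in the authors' deposited table (log2 fold change 5.40, standard error 1.13, adjusted p = 9.15e-05), and PGSC0003DMG400017342, at chromosome 7, 47724335 to 47726231, rose from 7.99 to 63.6 (log2 fold change 2.99, standard error 0.71, adjusted p = 0.000957). PGSC0003DMG400011438, at chromosome 10, 43787803 to 43788901, fell from 24.3 to 0.531 in the authors' deposited table (log2 fold change -5.52, standard error 0.81, adjusted p = 1.03e-09) and was at 39.1 in NG 7-Days. PGSC0003DMG400011243, at chromosome 10, 803109 to 804065, fell from 6.97 to 0.0306 in the authors' deposited table (log2 fold change -7.83, standard error 2.20, adjusted p = 0.0092), a call that was lost when the comparison was adjusted alone.

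By their medians, both sets called in NG 5-Days lay nearer to the control in NG 7-Days. Of the 131 transcripts that rose, 82 were lower in NG 7-Days than in NG 5-Days by the authors' deposited table, and 52 of the 167 that fell were higher, each by the test of those conditions. Both sets were selected for their NG 5-Days value, which that test uses again. A move back was thus favoured by the selection, and the counts are not separate evidence of a return. The set that rose had a median log2 level of 0.81 relative to the control in NG 7-Days, and the set that fell one of -0.86. Which direction held most calls depended on the processing. Rises were 41.8% of calls among transcripts with a recovered error in every condition, and on these transcripts 21.8% with median centring, 65.1% with a pseudocount of 1 (149 rises, 80 falls) and 85.8% with a pseudocount of 5 (344 rises, 57 falls). When the comparison was adjusted alone, 23 rose and 73 fell.

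On day 7 after NG, 3 transcripts differed from the control in the authors' deposited table and each had fallen. When the lines the table marks as not tested were adjusted along with the rest, 25 were called, 3 rises and 22 falls. PGSC0003DMG400033590, at chromosome 1, 75273081 to 75274481, fell from 7.94 to 1.13 in the authors' deposited table (log2 fold change -2.82, standard error 0.75, adjusted p = 0.00484). PGSC0003DMG400015490, at chromosome 2, 20113979 to 20115721, fell from 16.6 to 2.85 in the authors' deposited table (log2 fold change -2.54, standard error 0.67, adjusted p = 0.00412). The remaining one, at chromosome 3, 18603025 to 18605854, lay below the minimum level for naming and was picked out after its values were seen; in the authors' deposited table it fell from 3.61 to 0.418. All 3 had also fallen in NG 5-Days against the control. None was called when this comparison was adjusted alone.

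The low count on day 7 has limits that lie in the test. The authors' deposited table has 73 transcripts with an unadjusted p under 0.05 among 19964 tested, 7 higher and 66 lower, which is 0.366% of tests. It lists another 469 transcripts with a level of at least 5 and a change of at least 2-fold as not tested in this comparison, 367 of them higher in NG 7-Days.

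**Figure D2:**
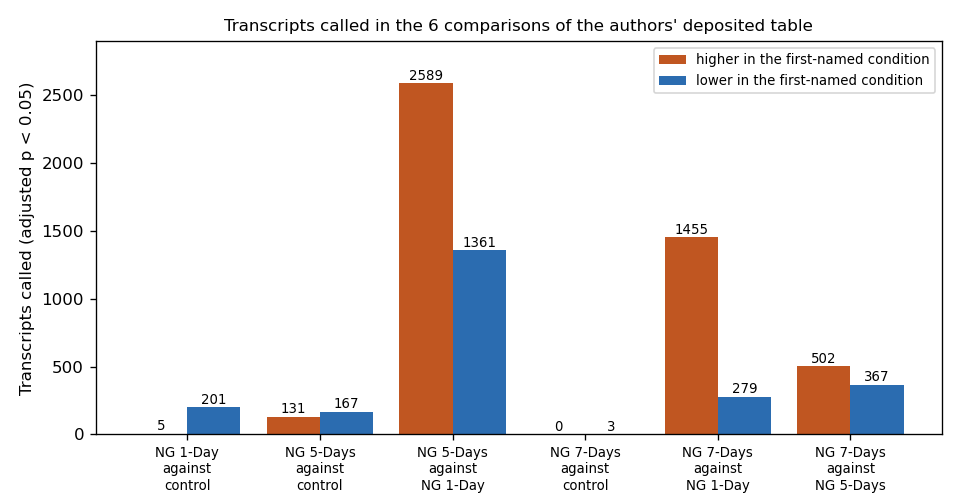
Number of transcripts called at an adjusted p under 0.05 (y axis) in each of the 6 comparisons of the authors' deposited table (x axis), with bars for those higher and lower in the first-named condition. The comparison of NG 5-Days with NG 1-Day has 2589 higher and 1361 lower, and NG 7-Days against the control has 0 higher and 3 lower.

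Most calls lay between the NG days. From NG 1-Day to NG 5-Days 2589 transcripts rose and 1361 fell among 19705 tested in the authors' deposited table, with median log2 fold changes of 1.79 and -1.18. From NG 1-Day to NG 7-Days 1455 rose and 279 fell in the authors' deposited table, and from NG 5-Days to NG 7-Days 502 rose and 367 fell. With a pseudocount of 5 the last of these turned to 306 rises and 404 falls. Of the 100 most abundant transcripts, each with a mean level of at least 723, 7 rose and 17 fell from NG 1-Day to NG 5-Days among the 92 tested, and none changed from NG 1-Day to NG 7-Days or from NG 5-Days to NG 7-Days by the authors' deposited table. The rises to NG 5-Days were 65.5% of calls, against 65.2% among transcripts with recovered errors and 50.9% of those after median centring. Among the 18223 transcripts with recovered errors, on which centring was run, the median level was 0.15 (log2) higher in NG 5-Days than in NG 1-Day, 0.12 higher in NG 7-Days than in NG 1-Day and 0.10 higher in NG 5-Days than in the control. The median log2 change over all transcripts tested between NG 1-Day and NG 5-Days was 0.041.

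The control lay between NG 1-Day and the later condition for most of these transcripts. Of the 2558 that rose to NG 5-Days and were above 0 in every condition, 92.3% had a control level in between, and of the 1357 that fell, 82.5% had. Of the 1421 that rose to NG 7-Days, 99.7% had a control level in between. In draws with no true difference, the 3386 transcripts most different between NG 1-Day and NG 5-Days had the control in between in 34.7% to 37.3% with the recovered errors, and in 83.8% to 86.1% with a control drawn without error. The observed share on the same footing was 91.0%.

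Called transcripts lay next to each other among tested transcripts more often than calls placed at random. From NG 1-Day to NG 5-Days there were 640 adjacent pairs called in the same direction, against 419 expected (permutation p = 1e-04, the smallest that 10000 shuffles can give). From NG 5-Days to NG 7-Days there were 62 against 18.8, and from NG 1-Day to NG 7-Days 176 against 109 (permutation p = 1e-04 for each). NG 5-Days against the control had 12 against 2.25 (permutation p = 1e-04), NG 1-Day against the control 6 against 2.03 (permutation p = 0.016), and NG 7-Days against the control had no pair among its 3 calls. When untested transcripts were kept in the order, pairs from NG 1-Day to NG 5-Days were 481 against 298 expected (permutation p = 1e-04), and for NG 1-Day against the control 4 against 1.38 (permutation p = 0.0514), no longer past 0.05.

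The steepest fall among runs of 5 lay on chromosome 6, 52389133 to 52404584, where 5 tested neighbours within 15.5 kb fell from NG 1-Day to NG 5-Days by a median of 17.3-fold in the authors' deposited table. Their summed level was 976 in the control, 1024 in NG 1-Day, 61.5 in NG 5-Days and 254 in NG 7-Days. Runs were counted among tested transcripts, and 1 untested transcript lay within that one. On chromosome 7, 45028538 to 45054399, another 5, with 5 untested transcripts among them, fell by a median of 5.98-fold, from a summed level of 1250 to 158 in the authors' deposited table. Their summed level in the control was 491, below that in NG 1-Day. On chromosome 11, 42016326 to 42044327, 5 tested neighbours, with 2 untested transcripts among them, fell by a median of 5.82-fold, and 4 of them rose again from NG 5-Days to NG 7-Days in the authors' deposited table. This run was selected for low NG 5-Days values, which the later test uses again, so a rise was favoured by the selection. On chromosome 9, 27832512 to 27886380, the same 5 transcripts, with 1 untested among them, fell from NG 1-Day to both later conditions, by medians of 6.42-fold and 3.45-fold in the authors' deposited table.

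**Figure D3:**
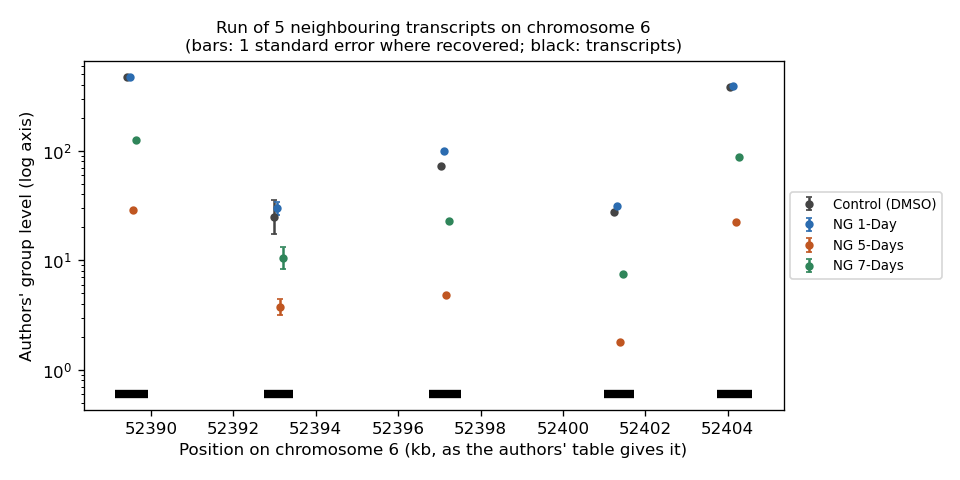
Authors' group level (y axis, log scale) of 5 transcripts, neighbours among those tested, on chromosome 6 by position (x axis, kb), in the 4 conditions, with points offset sideways and bars for 1 standard error for the single transcript where it could be recovered. The summed level goes from 1024 in NG 1-Day to 61.5 in NG 5-Days.

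The longest runs were of transcripts that rose. On chromosome 7, 43774689 to 43911016, 7 tested neighbours, with 3 untested transcripts among them, rose from NG 1-Day to NG 5-Days, 1 of them from a level listed at 0. Their median level was 1.58 in the control, 0.216 in NG 1-Day and 1.04 in NG 5-Days in the authors' deposited table. By this median the rise did not pass the control. On chromosome 8, 39874262 to 39919137, 6 neighbours rose from NG 1-Day to NG 7-Days, 1 of them from a level listed at 0. Their median level was 0.307 in the control, 0.0374 on day 1 and 0.807 on day 7 in the authors' deposited table, and the highest on day 7 was 1.75. On chromosome 4, 55945439 to 55983971, 6 rose by a median of 3.72-fold from NG 1-Day to NG 7-Days, from a summed level of 54.5 to 190 in the authors' deposited table. Their summed level in the control was 131. With no names paired to these identifiers, whether the members of a run are similar copies is not known here. The chromosome 7 run holds PGSC0003DMG401028957 and PGSC0003DMG402028957, and the chromosome 8 run PGSC0003DMG401003937 and PGSC0003DMG402003937. Each pair differs in 1 digit of the identifier, and whether such a pair belongs to 1 gene was not tested.

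The deposited test used larger errors for comparisons with the control than for those between NG days. These are model errors, and for NG 1-Day and NG 7-Days against the control they were wider than the scatter of the fold changes. The median standard error on the log2 scale was 0.56 in the control, 0.23 in NG 1-Day, 0.14 in NG 5-Days and 0.29 in NG 7-Days. At the median error a call needed a 3.58-fold, 3.42-fold and 3.77-fold change against the control for NG 1-Day, NG 5-Days and NG 7-Days. It needed a 1.80-fold change between NG 1-Day and NG 5-Days, 2.20-fold between NG 1-Day and NG 7-Days and 1.98-fold between NG 5-Days and NG 7-Days. Fewer calls against the control therefore do not show that levels were closer to it. Over tested transcripts, the median absolute log2 change from the control was 0.176 in NG 1-Day, 0.317 in NG 5-Days and 0.235 in NG 7-Days. Between NG days it was 0.408 (NG 1-Day to NG 5-Days), 0.340 (NG 1-Day to NG 7-Days) and 0.230 (NG 5-Days to NG 7-Days). By this median NG 1-Day and NG 7-Days lay nearer to the control than to each other, and NG 5-Days nearer to NG 7-Days than to the control.

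**Figure D4:**
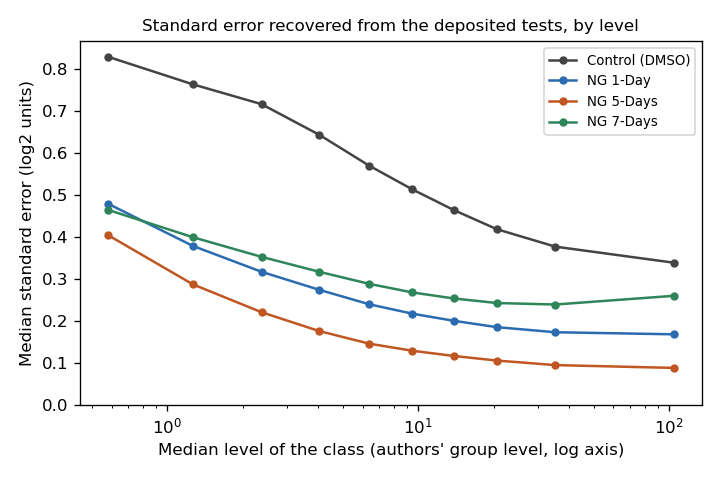
Median standard error on the log2 scale (y axis) against the median level of 10 classes of transcripts (x axis, log scale), 1 line per condition. The control lies above the NG conditions in every class, from 0.83 in the lowest class to 0.34 in the highest.

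The 3 comparisons with the control share that control, which by itself pushes their fold changes in the same direction. Across 17673 transcripts, which are not independent replicates, fold changes of NG 1-Day and NG 5-Days had a Pearson correlation of -0.384, where unchanged conditions simulated against the same control gave 0.838. The covariance was -0.141 against a simulated 0.369, a difference of -0.510. For NG 1-Day and NG 7-Days the correlation was -0.465 against 0.783 and the covariance differed by -0.483. The control was close to an average of these 2 conditions, as described below. Such a relation by itself gives their changes from the control opposite signs. The negative correlation is therefore not separate evidence of opposite responses. For NG 5-Days and NG 7-Days the correlation was 0.672 against 0.823, and the covariance differed by -0.183. The simulation drew on the recovered errors, which were too wide: those errors alone would put 3331 transcripts at 2-fold or more from the control in NG 7-Days, where 1338 were seen. The simulated covariances and the 3 differences are therefore overstated in size, and the last does not show that NG 5-Days and NG 7-Days shared less than unchanged conditions would. Of the transcripts called against the control, 13 had fallen in NG 1-Day and risen in NG 5-Days, where independent lists would share 0.981, and 5 had fallen in both, where they would share 1.19. Unchanged conditions drawn against the same control with the recovered errors shared 20 calls in the same direction and 0 in opposite directions. The 5 were therefore not an excess over these draws. Neither the independent lists nor the draws allow for a control close to an average of NG 1-Day and NG 7-Days. The 13 are therefore not separate evidence of a reversal. The control could not be divided, so part or all of any overlap in the same direction may come from it.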

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

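The tests of fold change size, of averaging in rising transcripts and of the share of low p-values were chosen after the results they measure were seen, and the change of the control error and the order with untested transcripts were added after the data were examined. Levels differed between NG conditions by the deposited test, which does not separate NG from elapsed time: 3950 transcripts differed between NG 1-Day and NG 5-Days, 1734 between NG 1-Day and NG 7-Days, and 869 between NG 5-Days and NG 7-Days. Of the 201 transcripts called lower than the control in NG 1-Day, 13 were called higher than the control in NG 5-Days.

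Few transcripts were called against the control, 507 over the 3 comparisons, against 869 between NG 5-Days and NG 7-Days. Smaller fold changes stay open: 1813, 3256 and 1338 tested transcripts were at 2-fold or more from the control in NG 1-Day, NG 5-Days and NG 7-Days, where the recovered errors alone would give 3030, 2952 and 3331, so such counts do not compare true fold sizes. With observed counts below those numbers for NG 1-Day and NG 7-Days, the errors were also wider than the scatter of the fold changes. Setting the control error to that of NG 7-Days gave 2259 calls, against 264 with the control's own error on the same transcripts, but it lowered the error of 98.4% of them and so had to raise the count, and the cause is not decided by it. A small difference from the control on day 7 stays open as the biological explanation, untested.

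For most transcripts called from NG 1-Day to NG 5-Days, 91.0% of those with recovered errors, the control lay in between. Scaling is argued against by 88.8% of them after quantile normalization. If the authors' model errors hold, chance as the source of the differences is argued against by 33.9% of tests with an unadjusted p under 0.05. Those errors, smallest in NG 5-Days (median 0.14, log2), could not be checked against library values. Variation between libraries beyond them is therefore not excluded. The 0 calls in 20 draws with 1 true level per transcript follow from the adjustment. How much selection adds to the share in between is open. The draws reached 37.3% with the recovered errors, which were too wide for NG 1-Day and NG 7-Days against the control. They reached 86.1% with a control without error, which no control is. A control averaged over libraries resembling NG 1-Day and NG 7-Days could also give it, and medians of the rise from control to NG 7-Days were only 0.077 (log2) apart between steep and moderate risers, but NG 7-Days set between NG 1-Day and NG 5-Days levelled off too, at 0.23. Falling transcripts passed the bound set against averaging, at 4.50, but on 1 transcript, too few to decide. A dip after NG followed by an overshoot stays open as the biological explanation, untested, since the table holds no library values and no later DMSO tubers.

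Transcripts adjacent among those tested were called together in 4 comparisons with 10 or more such pairs. Chance placement is argued against by a permutation p of at most 1e-04 in these 4, the smallest the shuffles can give. Overlapping loci are argued against because only neighbours that do not overlap were counted, and the lowest ratio of observed to expected pairs was 1.53. Reads shared between similar copies cannot be told apart from joint regulation of neighbours, because 0 called transcripts come with a sequence in the table. Joint regulation by NG or time therefore remains a possible explanation, not tested here.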

How the results depend on the processing

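The analyses of adjustment, control error, pseudocount 1, overlapping loci and transcripts with recovered errors were chosen after seeing the data. No paired analysis was possible because the table gives 1 value per condition and its columns carry no replicate numbers. For the same reason the count tools, limma, the fit of only the groups compared, leaving out libraries and the gene list tests were not run. Of the 81 counts under 15 alternatives, 53 stayed within 1.5 times the reported count. No named transcript changed sign, and 8 of their 101 values lost the call. Most alternatives kept the deposited fold change, so a sign could change only under median centring, quantile normalization or a pseudocount. Those were run only on transcripts with recovered errors. The named transcripts without them, among them the named falls on day 1 and the named rises in NG 5-Days, were not rechecked there.

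For NG 1-Day against the control (206 calls) the count was 106 at an adjusted p under 0.01, 123 with a level of at least 5 in 2 conditions, 82 adjusted alone and 471 with the NG 7-Days error in place of the control's. Restricting to transcripts with recovered errors gave 96, by construction fewer; on these, median centring gave 90, quantile normalization 50, and pseudocounts of 0.1, 1 and 5 gave 85, 34 and 11. For NG 5-Days against the control (298) the count was 118 at 0.01, 467 without a filter, 96 adjusted alone and 1737 with the NG 7-Days error. With recovered errors it was 165, with median centring 174, with quantile normalization 174, and pseudocounts of 0.1, 1 and 5 gave 178, 229 and 401, the last with 136 of the reported calls and 85.8% rises. For NG 7-Days against the control (3) it was 25 without a filter, 1 with a pseudocount of 5, 0 adjusted alone, where 73 had an unadjusted p under 0.05, and 51 with the NG 7-Days error.

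From NG 1-Day to NG 5-Days (3950) a level of at least 5 left 2535. From NG 1-Day to NG 7-Days (1734) it left 865, and 0.01 left 1115; rises were 73.5% of calls after quantile normalization, against 85.6% before. From NG 5-Days to NG 7-Days (869) it left 484, 0.01 left 449, and no filter gave 1413; with a pseudocount of 5 rises were 43.1% of its calls, against 56.1% without one. Apart from the thresholds, filters and restrictions, which change the number tested or called by construction, the cause was not tested. Depth is unknown, so what it limits is not known.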

Other observations

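The table lists some abundant transcripts as not tested. Of transcripts with a level of at least 5 in both conditions, 5.08% were not tested for NG 1-Day against the control, 3.17% for NG 5-Days and 4.64% for NG 7-Days against it. Most were tested in another comparison: 465 of the 535 for NG 7-Days against the control. Of the 201 transcripts that fell on day 1, 103 had no test on day 7 against the control.

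A few of the 10636 transcripts listed at 0 in NG 1-Day had a level of at least 1 later. There were 22 listed at 0 in NG 1-Day with a level of at least 1 in NG 5-Days, the highest at 61.3, and 26 with such a level in NG 7-Days, the highest at 28.7. The reverse, a level of at least 1 in NG 1-Day and 0 later, was seen for 11 in NG 5-Days and 3 in NG 7-Days.

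The deposited p-values for NG 7-Days against the control were fewer at the low end than chance alone gives: 0.366% lay under 0.05. For NG 1-Day against the control the share was 3.25%, and for NG 5-Days against it 7.52%, above that level. For NG 7-Days the errors used by the test were thus wide for the scatter of the fold changes across transcripts.

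The control profile was close to an average of NG 1-Day and NG 7-Days, a relation looked at after the data were seen. In an earlier least squares fit of each of the 4 conditions as a mix of the other 3, over 15986 transcripts, the median residual (log2) was 0.12 for the control, 0.14 for NG 7-Days, 0.66 for NG 5-Days and 0.99 for NG 1-Day. NG 7-Days was thus fitted about as closely as the control. That fit put a weight of 0.456 on the control and 0.486 on NG 5-Days. The control's fit put 0.518 on NG 1-Day and 0.417 on NG 7-Days. Since each fit used the other condition, the close fit of NG 7-Days does not count against such an average. With weights set on 7601 transcripts of odd chromosomes, an arithmetic average with a weight of 0.608 on NG 1-Day left a median residual of 0.11 (log2) on 459 called transcripts of even chromosomes, and a geometric average 0.14. NG 1-Day alone left 0.74 and NG 7-Days alone 0.71 on these, which were selected for a difference between the ends. Over all 7154 transcripts of even chromosomes in the fit the arithmetic average left 0.084, the geometric one 0.086, NG 1-Day alone 0.136 and NG 7-Days alone 0.193. Transcripts rising 4 or more (log2) from NG 1-Day to NG 7-Days were 150, and all 150 were above the control on day 7, by a median of 0.98. An equal rise in these transcripts on day 7 is a candidate explanation too, since the medians differed by only 0.077 between the classes under either account.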
